A study of Mus musculus with 18 samples.

How the data were processed

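RNA was measured by sequencing in the apex of 18 hearts of C57BL/6 mice, an inbred laboratory strain, collected 1 day after myocardial infarction (MI) or a sham operation. Per the labels, total RNA was extracted with Trizol from frozen tissue of perfused hearts, made into RNA Access libraries, which enrich coding transcripts by hybridisation capture, and read as single reads of 50 bases on a BGISEQ-500 instrument. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the mouse genome build GRCm38.p6, without saying what each was used for. The role of each tool and the annotation release are not given in the sources used here.

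Each library came with 2 files deposited by the authors, one with a value for each of 19197 genes and one with a value for each of 64405 transcripts. The deposited values were FPKM, read counts divided by transcript length and by the mapped reads of the library, rounded to 2 decimals by the authors and, as far as the values show, not scaled further between libraries. The header does not name the unit. It was checked from the values: their sum differed between libraries, from 516274 to 584701, whereas the sum of value times transcript length differed little, with a coefficient of variation of 0.21%, as FPKM and not TPM would give. Gene values were used for all comparisons, and transcript values only to check the unit and estimate depth. Of the gene identifiers, 19051 (99.2%) matched a RefSeq gene table of GRCm38.p6, from which coordinates were taken, and 26 symbols that had turned into dates were restored through their identifiers.

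The files hold no counts, so the number of reads per library is not stated in them. Low values of 1112 genes with a single short transcript fell on steps of 1 read, and the spacing of those steps gave an estimate of 9600000 to 13900000 mapped reads per library. A spacing of double or 0.5 times the true one cannot be excluded by this method, so the estimates were searched only between 8000000 and 16000000. They were 9600000 to 10600000 in the sham hearts, 11200000 to 13900000 in the infarcted hearts given vehicle and 10000000 to 12800000 in the infarcted hearts given DCA. Genes above 0 numbered 15730 to 16229 per library. FPKM without counts gives no counting interval, so all errors are spreads between hearts.

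Samples were grouped by the tissue and treatment labels into sham_vehicle, MI_vehicle and MI_DCA, 6 libraries each, and numbered by their titles. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples. Pearson correlations between libraries of a group, over genes on the log scale, ranged from 0.965 to 0.996, and no pair of libraries was identical. The planned test was a quasi-likelihood test of expected counts. Because the files hold FPKM, the setting planned for that unit was used in its place: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 6 of the 12 libraries compared. Each of 3 comparisons was fitted on its own 2 groups with no covariates, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes below the filter were compared with a two-sided exact permutation test over all 924 regroupings of the 12 hearts, whose smallest possible p is 0.00217.

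Before the data were examined, 44 gene lists were fixed, among them markers of other cell types of the heart, and tested with camera in limma against the remaining genes, with a preset correlation between genes of 0.01, an intensity trend and adjustment over the lists of a comparison. Lists with fewer than 3 measured members were not tested. The test asks whether the genes of a list rank higher or lower than other genes, so its direction can differ from the sign of the list's median. It was repeated with an estimated correlation. A score per heart was the mean log2(FPKM + 1) over the measured members of a list, compared between groups with the same exact permutation test and adjusted over 41 scores. The rule for named genes was also fixed in advance. It took, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean FPKM of at least 10 or, where no gene was called, the 5 with the smallest p in each direction. It added the 3 called members of each list with the largest change, and 13 genes reported in every comparison. The mean minimum had been written for counts scaled by library size and was applied to FPKM.

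The test was tried on simulated data for each comparison, with 200 genes changed by known folds. The changed genes were drawn from those above a minimum mean, which left out genes of low expression. Noise was drawn independently for each gene. At a simulated log2 fold change of 1, the test recovered 96% of changed genes for infarction against sham, 86% for DCA against vehicle and 86% for DCA against sham, and at 0.5 it recovered 64%, 48% and 36%. False calls numbered 10, 11 and 7 among 11969, 12004 and 11842 genes. The recovery rates are those of genes drawn at random above that mean. Genes that spread more between hearts, such as Il1b, Il6, S100a8 and Nppb for DCA against vehicle, would be recovered less often.

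The alternatives tried were a pseudocount of 0.1, no filter on low values, all 18 libraries in one fit, the number in the titles as a block, a minimum log2 fold change of 1, leaving out each library in turn and, for lists, an estimated correlation. Median-ratio scaling, quantile normalization, array quality weights, a mean FPKM of at least 10 and a cardiomyocyte score as a covariate were added after the data had been seen. Fold changes of the 2 comparisons that share the MI_vehicle libraries were set against 100 simulated unchanged groups and against all 20 divisions of those libraries into 2 sets of 3. For each count of called genes, 100 splits of the 12 libraries were refitted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the files. A test of the class II MHC genes against the number of cells that express them was run and is not reported here.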

Results

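Expression of 19197 genes was measured in the apex of 18 mouse hearts 1 day after surgery. The hearts formed 3 groups of 6: sham-operated mice given vehicle (sham_vehicle), mice with myocardial infarction (MI) given vehicle (MI_vehicle), and mice with MI given DCA at 10 mg/kg per day (MI_DCA). The labels do not spell out DCA. It is taken here as deoxycholic acid, a secondary bile acid, because the study names it together with TGR5, the membrane bile acid receptor encoded by Gpbar1. The study concerns this signalling and inflammation after infarction. The estimated depth was 9600000 to 13900000 mapped reads per library, and 9600000 to 10600000 in the sham hearts. Values are FPKM as deposited, given as mean ± SD with n = 6 per group, and fold changes are on the log2(FPKM + 1) scale with their standard error (SE) and the adjusted p of limma.

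After infarction many single genes of cardiac stress, matrix remodelling and inflammatory cells were higher, and many of the contractile and oxidative machinery were lower. Bulk tissue does not separate a change in cell proportions from regulation within cells, and this was not tested for infarction against sham. As lists, 15 ranked higher and 7 lower by camera with its preset correlation, and none passed with an estimated correlation (smallest adjusted p = 0.416). Scored per heart, 31 of 41 lists differed from sham after adjustment by the exact permutation test (smallest adjusted p = 0.00444). That test regroups whole hearts and so keeps the correlation between genes. It asks whether a list differs from sham, and camera whether it differs from other genes. The largest rise was that of Sprr1a, a small proline-rich protein gene induced in stressed cardiomyocytes (chromosome 3, 92483954 to 92485881, GRCm38.p6), from 3.17 ± 2.22 FPKM in sham hearts to 283 ± 187 in MI_vehicle hearts (log2 fold change 5.76, SE 0.64, adjusted p = 4.3e-05). It was followed by Nmrk2, a kinase of NAD synthesis in muscle (4.92, SE 0.47), Spp1, which encodes osteopontin (4.43, SE 0.51), and Ankrd2, a stretch-responsive muscle gene (4.10, SE 0.52). Timp1, an inhibitor of matrix metalloproteinases, rose by a log2 fold change of 3.83 (SE 0.38). AA467197 (3.75, SE 0.51), the arginase gene Arg1 (3.72, SE 0.47) and the macrophage chitinase-like gene Chil3 (3.70, SE 0.45) completed the 8 largest rises among genes with a mean of at least 10 FPKM. The adjusted p of these genes ranged from 2.06e-05 to 0.000129, and all 8 separated the 6 MI_vehicle hearts from the 6 sham hearts.

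Among genes with a mean of at least 10 FPKM, the largest falls were those of Clec3b, which encodes tetranectin (log2 fold change -2.62, SE 0.58, adjusted p = 0.00215), and Kcnip2, a subunit of the channel for the transient outward potassium current (chromosome 19, 45792346 to 45816422). Kcnip2 went from 121 ± 9.28 FPKM in sham hearts to 26.2 ± 25.2 in MI_vehicle hearts (-2.58, SE 0.42, adjusted p = 0.000347). Lgals4 (-2.44, SE 0.49), Ces1d (-2.26, SE 0.31), A530016L24Rik (-2.23, SE 0.40), Asb14 (-2.21, SE 0.47), Lrtm1 (-2.17, SE 0.41) and Ucp3, a mitochondrial uncoupling protein gene (-2.09, SE 0.70), followed, with adjusted p from 0.000129 to 0.02. The hearts of both groups overlapped in Lrtm1 and Ucp3. Myh6, the main myosin heavy chain gene of the adult mouse ventricle (chromosome 14, 54941921 to 54968017), fell from 4436 ± 214 to 2110 ± 973 FPKM (-1.19, SE 0.24, adjusted p = 0.0011).

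All 16 measured cardiac stress and fetal genes rose (16 adjusted over the list alone, median log2 fold change 2.31, adjusted p = 6.2e-06 by camera and 0.416 with an estimated correlation). Nppa, the atrial natriuretic peptide gene, rose by 3.37 (SE 0.46) and Nppb, the brain natriuretic peptide gene (chromosome 4, 147985786 to 147987205), by 3.28 (SE 0.50), from 179 ± 64.8 to 2057 ± 1156 FPKM. Of 24 cardiomyocyte markers 19 fell, among them Hrc, Tcap and Pln, and 2 rose, Actc1, the cardiac actin gene (0.56, SE 0.17), and Smpx (0.73, SE 0.16). The counts were 19 and 2 adjusted over the list alone as well (adjusted p = 1.31e-06, and 0.416 with an estimated correlation). All 25 genes of fatty acid oxidation fell (25 adjusted over the list alone, median -1.02), as did 29 of 30 oxidative phosphorylation subunits (30 adjusted over the list alone, median -0.63), with adjusted p = 2.07e-11 and 1.53e-11 and 0.416 each with an estimated correlation. Of 15 PPAR target genes 12 fell and Angptl4 rose (12 and 2 adjusted over the list alone, adjusted p = 0.000116, and 0.439 with an estimated correlation). Acot1 (-1.97, SE 0.45) was among those that fell. Of 23 ion channel and calcium handling genes 13 fell and 2, among them Slc8a1, rose (13 and 2 adjusted over the list alone, adjusted p = 7.68e-05, and 0.416 with an estimated correlation). Of 17 circadian clock genes 10 fell, among them Hlf and Per1, and 2, Bhlhe41 and Nfil3, rose (10 and 2 adjusted over the list alone, adjusted p = 0.00537, and 0.416 with an estimated correlation).

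Genes of the inflammatory response rose. All 22 markers of infiltrating monocytes and macrophages were higher (22 adjusted over the list alone, median 1.88, adjusted p = 3.67e-09), led by Arg1, Chil3 and the monocyte antigen gene Ly6c2 (3.69, SE 0.29). So were all 16 proinflammatory cytokine and chemokine genes past the filter, of 23 listed (16 adjusted over the list alone, median 2.14, adjusted p = 8.88e-06). Both lists had an adjusted p = 0.416 with an estimated correlation. Ccl2, the main monocyte chemoattractant gene (chromosome 11, 82035577 to 82037452), went from 6.2 ± 2.87 to 74.5 ± 27.5 FPKM (3.42, SE 0.33) and Ccl7 rose by 3.36 (SE 0.33). Il1b, the interleukin-1 beta gene (chromosome 2, 129364569 to 129371164), went from 0.957 ± 0.27 to 14.2 ± 10.7 FPKM (2.70, SE 0.34, adjusted p = 8.43e-05). Il6 (2.16, SE 0.35) and the neutrophil chemokine gene Cxcl2 (1.98, SE 0.40) rose too. Of 23 listed neutrophil markers 13 were measured, of which 12 rose and G0s2 fell (12 and 1 adjusted over the list alone, adjusted p = 0.00171, and 0.439 with an estimated correlation). Genes below 1 FPKM in every sham heart passed the filter only with at least 1 in all 6 MI_vehicle hearts, so these counts favour rises. S100a9 rose by 3.36 (SE 0.53) and S100a8 by 2.87 (SE 0.54). Tnf and Nlrp3, the gene of an inflammasome sensor, lay below the filter. Tnf measured 0.315 ± 0.149 FPKM in sham and 1.5 ± 0.66 in MI_vehicle hearts, and Nlrp3 0.38 ± 0.139 and 1.59 ± 0.505, each with an exact permutation p = 0.00217, the smallest that 6 against 6 hearts can give.

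Of 26 interferon-stimulated genes 23 rose (23 adjusted over the list alone, median 1.17, adjusted p = 9.15e-08), and Cxcl10 had the smallest adjusted p of all genes (2.78, SE 0.14, adjusted p = 2.23e-07). Of 22 leukocyte adhesion and migration genes 18 rose and Jam3 fell (20 and 1 adjusted over the list alone, adjusted p = 2.51e-06). Of 20 NF-kB pathway and feedback genes 17 rose and Sod2 fell (17 and 1 adjusted over the list alone, adjusted p = 0.000286). Of 20 IL-1 signalling and inflammasome genes 15 rose (15 and, lower, 1 adjusted over the list alone, adjusted p = 0.00117). They were led by Il1b, Il1r2 and the receptor antagonist gene Il1rn (2.28, SE 0.22). Of 11 pyroptosis and necroptosis genes 9 rose, among them Zbp1, Ripk3 and Mlkl (10 adjusted over the list alone, adjusted p = 0.00171). These 5 lists had an adjusted p = 0.416 with an estimated correlation. Of 20 activated fibroblast and matrix remodelling genes 18 rose (19 adjusted over the list alone, adjusted p = 7.54e-06, and 0.416 with an estimated correlation), with Tnc, which encodes tenascin C, at 3.70 (SE 0.38). Of 24 cell cycle genes 22 rose, led by Mcm5, Mcm6 and Mcm3 (23 adjusted over the list alone, adjusted p = 1.49e-05, and 0.461 with an estimated correlation). Of 25 ribosomal protein genes 24 rose (25 adjusted over the list alone, adjusted p = 1.15e-05, and 0.483 with an estimated correlation). Ribosomal protein genes share reads with many pseudogenes, so their values are uncertain. Of 20 genes of the unfolded protein and integrated stress response 15 rose and 2, Herpud1 and Chac1, fell (15 and 2 adjusted over the list alone, adjusted p = 0.00134, and 0.446 with an estimated correlation). Of 22 apoptosis genes 14 rose and 2, Fas and Birc2, fell (14 and 2 adjusted over the list alone, adjusted p = 0.026, and 0.484 with an estimated correlation). Of 24 glycolysis genes and hypoxia targets 15 rose, led by the lactate transporter gene Slc16a3 (3.15, SE 0.38), and 3 fell (16 and 3 adjusted over the list alone, adjusted p = 0.0282, and 0.598 with an estimated correlation). That call was lost without sham_vehicle replicate 3 (adjusted p = 0.0589).

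Markers of the other cells of the heart gave no call as lists by camera, with adjusted p from 0.125 to 0.987, except adipocyte markers. Of those, 2 of 3 fell (2 adjusted over the list alone, adjusted p = 0.0282, and 0.416 with an estimated correlation), and the call was lost with median-ratio scaling (0.0594) and quantile normalization (0.0798). Of 13 resident cardiac macrophage markers 3 rose and 4, among them Cd163, fell (3 and 4 adjusted over the list alone). Of 19 fibroblast markers 7 rose and 6, among them Scara5 (-2.12, SE 0.34) and Gsn, fell (7 and 6 adjusted over the list alone). Of 21 endothelial markers 5 rose and 6 fell (3 and 4 adjusted over the list alone). Of 16 smooth muscle and pericyte markers 4 rose and 6 fell (4 and 6 adjusted over the list alone). Of 10 mast cell and dendritic cell markers 6 rose (6 adjusted over the list alone), among them the class II MHC gene H2-Ab1 (0.73, SE 0.11), which other antigen-presenting cells express too. Of 6 epicardial markers 1 rose, Aldh1a2, and 1 fell (1 and 1 adjusted over the list alone). Of 7 erythroid markers 1 fell (1 adjusted over the list alone). Of 8 atrial and conduction markers 2 rose and 2 fell (2 and 2 adjusted over the list alone), and of 8 Schwann and neuronal markers 2 rose and 2 fell (2 and 2 adjusted over the list alone). Of 5 skeletal muscle markers 2 rose (2 adjusted over the list alone), and of 4 sex-linked transcripts 1, Uty, fell (1 adjusted over the list alone). Both measured platelet markers, Ppbp and Pf4, rose, but 2 members are too few for the list test, as is the 1 measured member of the lymphocyte and NK list and of the nuclear and RNA quality list. Neither passed over all genes, and adjusted over the list alone the second did. No lung epithelial marker passed the filter. Direction differed between test and median for resident macrophage, fibroblast, smooth muscle and epicardial markers, which ranked below other genes at medians of 0.18, 0.10, 0.00 and 0.41, and between median (-0.22) and mean (0.15) for atrial markers. The fibroblast and smooth muscle medians turned negative with both scalings (fibroblast -0.01 and -0.07, smooth muscle -0.13 and -0.16). Against sham itself, scores per heart were higher for mast cell and dendritic cell (difference 0.454), lymphocyte and NK (0.287), atrial (0.153) and skeletal muscle markers (0.386). They were lower for adipocyte markers (-0.785) and sex-linked transcripts (-0.181), all with adjusted exact permutation p from 0.00683 to 0.0344. The other marker scores did not pass (0.0638 to 0.952). Scores used the filter over all 18 libraries, which kept 4 lymphocyte members.

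The remaining lists gave no call by camera, which compares a list with the other genes. Against sham itself, scores per heart were higher for oxidative stress (difference 0.579), heat shock (0.675), anti-inflammatory (0.597) and cAMP genes (0.35). Each had an adjusted exact permutation p of 0.00444. The scores of acute phase, glucocorticoid and bile acid genes did not pass (0.17 to 0.892). Of 21 oxidative stress response genes 14 rose and 4 fell (14 and 4 adjusted over the list alone, adjusted p = 0.0717). The list was called with median-ratio scaling (0.0211), quantile normalization (0.00572) and without sham_vehicle replicate 1 (0.0382), MI_vehicle replicate 1 (0.0439) or MI_vehicle replicate 2 (0.0328). Of 15 heat shock genes 9 rose, led by Hspb1 (2.78, SE 0.39), and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.228, and 0.0355 with quantile normalization). Of 19 anti-inflammatory and resolution genes 11 rose and 5 fell (11 and 6 adjusted over the list alone, adjusted p = 0.282). Of 17 cAMP and CREB target genes 8 rose, among them Atf3 and Fos, and 5 fell (8 and 5 adjusted over the list alone, adjusted p = 0.816). Of 16 acute phase and complement genes 5 rose and 6 fell (5 and 6 adjusted over the list alone, adjusted p = 0.276), and of 15 glucocorticoid response genes 4 rose and 6 fell (4 and 6 adjusted over the list alone, adjusted p = 0.228). Acute phase and glucocorticoid genes ranked below other genes at medians of 0.05 and 0.14. The cAMP median of 0.06 and the acute phase median turned negative with both scalings (cAMP -0.06 and -0.10, acute phase -0.09 and -0.04), and the glucocorticoid median with quantile normalization (-0.02). Of 7 measured bile acid receptor and handling genes Abcc3 and S1pr2 were among 3 that rose, and Cyp27a1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.844). Gpbar1 (chromosome 1, 74278600 to 74279589) lay near the lower limit of detection, at 0.05 ± 0.0837 FPKM in sham and 0.337 ± 0.291 in MI_vehicle hearts (exact permutation p = 0.0281). Nr1h4, the nuclear bile acid receptor gene, measured 0.567 ± 0.17 and 0.332 ± 0.0831 FPKM (exact permutation p = 0.00866). Col1a1, a collagen gene, measured 110 ± 40 and 180 ± 64.7 FPKM (0.71, SE 0.26, adjusted p = 0.0285), and its call was lost with median-ratio scaling (0.0683) and without sham_vehicle replicate 1 (0.0653), 3 (0.0558) or 4 (0.066) or MI_vehicle replicate 1 (0.0627) or 6 (0.0654).

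Members named because they moved against their list were picked after their values were seen. In all, 4583 of 11969 tested genes were higher and 2408 lower in MI_vehicle than in sham hearts, 58.4% of those tested, and 785 and 292 of them at a log2 fold change of at least 1. The share of higher genes among those called was 65.6% as deposited, 49.5% with median-ratio scaling (3376 higher and 3446 lower) and 46.3% with quantile normalization (3189 and 3693), which moved the median of all genes by -0.13 and -0.15, so the balance of rises and falls depends on the scaling.

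**Figure D1:**
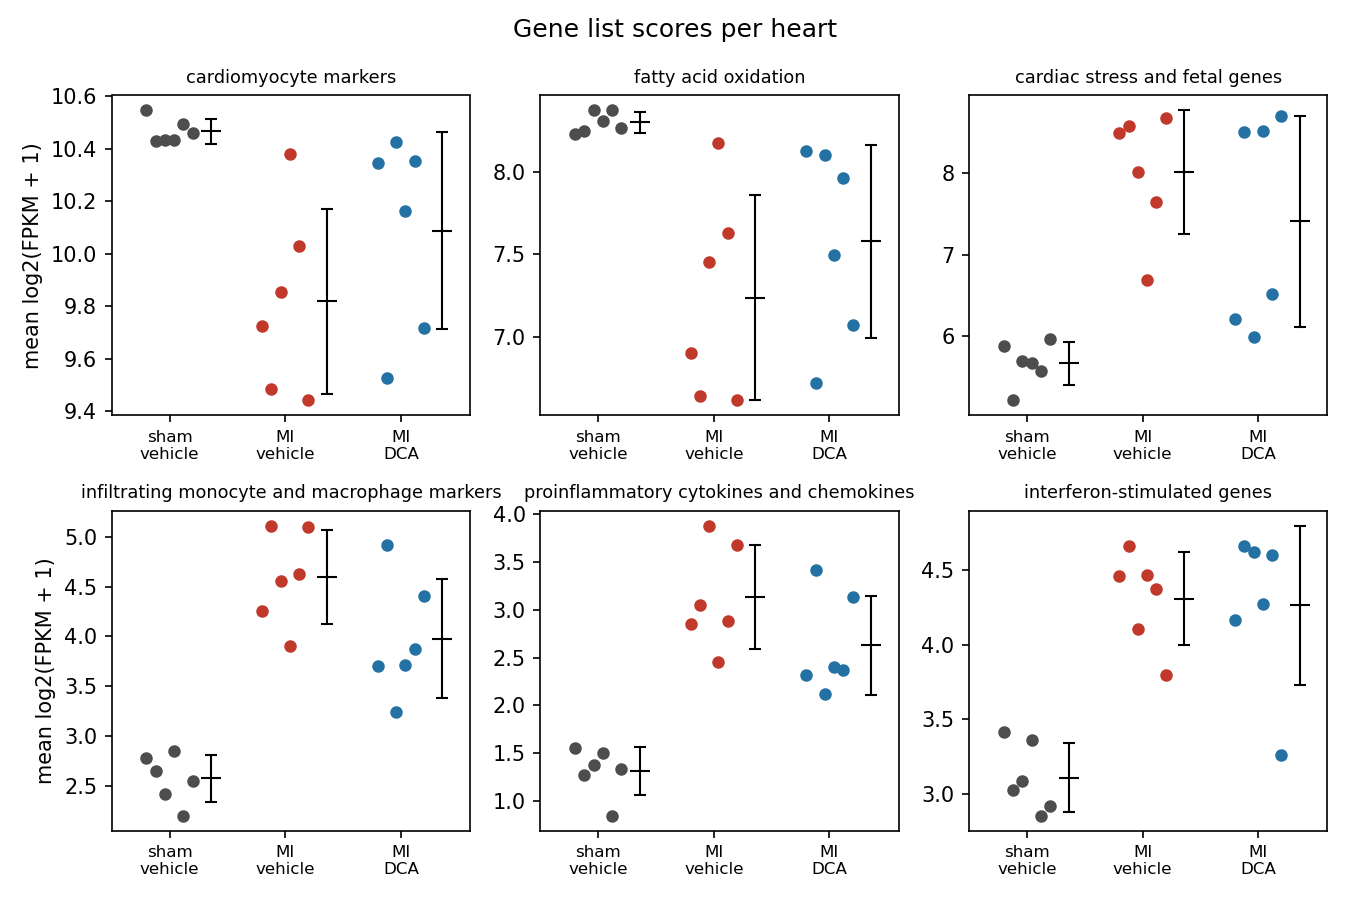
Scores of 6 gene lists per heart (mean log2(FPKM + 1) over the measured members, vertical axes) in the 3 groups (horizontal axes), 1 point per heart, with the group mean as a horizontal mark and 1 SD as whiskers. The cardiac stress score ranged from 5.22 to 5.97 in sham hearts and from 6.69 to 8.67 in MI_vehicle hearts, and from 5.99 to 8.69 in MI_DCA hearts.

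DCA treatment was then compared with vehicle among infarcted hearts. No gene passed the threshold in limma: 0 of 12004 genes were higher and 0 lower, the smallest adjusted p was 0.301, and 1299 genes had an unadjusted p under 0.05 (192 higher and 1107 lower in MI_DCA hearts) where chance gives 600 on average. Genes are not independent, so a count under chance can lie far from 600. The median log2 fold change of all genes was -0.065 as deposited. Median-ratio scaling and quantile normalization moved fold changes by a median of 0.069 and 0.085, so the balance of higher and lower genes may depend on the scaling. Of the 924 regroupings of the 12 MI hearts, 190 (20.6%) gave a larger mean absolute fold change than the real one. The named inflammatory genes measured lower on average in MI_DCA hearts and were not called, though most were with array quality weights (below). Il1b was 7.81 ± 5.88 FPKM in MI_DCA and 14.2 ± 10.7 in MI_vehicle hearts (log2 fold change -0.75, SE 0.46, adjusted p = 0.542), Ccl2 was 53.3 ± 36.5 and 74.5 ± 27.5 (-0.63, SE 0.40, adjusted p = 0.552), and Il6 was 2.19 ± 1.7 and 5.76 ± 5.16 (-0.95, SE 0.46, adjusted p = 0.465). Tnf (-0.33, SE 0.16), Cxcl2 (-0.72, SE 0.47), Nlrp3 (-0.36, SE 0.17), S100a8 (-0.99, SE 0.58) and S100a9 (-0.86, SE 0.56) had adjusted p from 0.461 to 0.56. Nppb was 1331 ± 1238 and 2057 ± 1156 FPKM (-1.24, SE 0.88, adjusted p = 0.578), Myh6 2734 ± 1279 and 2110 ± 973 (0.34, SE 0.36, adjusted p = 0.685), and Col1a1 119 ± 29 and 180 ± 64.7 (-0.56, SE 0.23, adjusted p = 0.439). Gpbar1 measured 0.238 ± 0.195 and 0.337 ± 0.291 FPKM (exact permutation p = 0.52) and Nr1h4 0.368 ± 0.36 and 0.332 ± 0.0831 (exact permutation p = 0.911).

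The genes with the smallest p in each direction are given as values and not as calls. Higher in MI_DCA hearts were Aldoart1 (0.60, SE 0.09, adjusted p = 0.301), Gm14440 (0.54, SE 0.13), Ramp2, a co-receptor for adrenomedullin in endothelium (0.42, SE 0.10, at 102 ± 11.2 against 76.2 ± 8.94 FPKM), Jcad, an endothelial junction gene (0.31, SE 0.08), and Gapdh-ps15 (0.57, SE 0.14), the last 4 at an adjusted p of 0.407. Lower were Zfp991 (-0.65, SE 0.11, adjusted p = 0.345), Sin3b (-0.34, SE 0.06), Maged2 (-0.52, SE 0.11), Septin6 (-0.46, SE 0.09) and Id2, an inhibitor of DNA-binding transcription factors (-0.57, SE 0.12), the last 4 at an adjusted p of 0.402. Aldoart1, Gapdh-ps15 and Zfp991 resemble other genes closely enough to share reads with them, and their values are uncertain.

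Array quality weights, which give less weight to hearts far from their group and were tried after the data had been seen, changed this count to 1623 higher and 3747 lower genes. With them Il1b (-1.24, adjusted p = 0.0394), Il6 (-1.62, 0.0147), Tnf (-0.51, 0.0109), Ccl2 (-1.23, 0.00608), Cxcl2 (-1.43, 0.0352), Nlrp3 (-0.55, 0.00872) and S100a8 (-1.40, 0.043) were called lower, and S100a9 was not (-1.23, 0.066). Nppb (-2.75, 0.00726) and Col1a1 (-0.53, 0.044) were called lower and Myh6 higher (0.84, 0.0184), as were the 10 genes of smallest p above in their directions. The fold changes of Il1b, Il6, Tnf, Ccl2, Cxcl2, Nlrp3, Nppb and Myh6 grew by over 1.5 times. Of 100 splits of the same 12 hearts fitted with such weights, 19 gave at least 5370 genes, the real one included, so the weighted count was not larger than other groupings of these hearts gave. The lowest weights fell on MI_DCA replicates 2 (0.27), 6 (0.31) and 4 (0.59) and on MI_vehicle replicate 4 (0.36). On the first principal component (below), those MI_DCA hearts lay farthest from sham in their group (49.5, 40.6 and 16.7). MI_vehicle replicate 4 lay nearest to sham in its group (-15). The weights thus discounted the hearts that lay against a DCA difference on that axis, which by itself enlarges the fold changes along it. Without MI_vehicle replicate 5, 1 gene was lower.

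As groups, 6 lists ranked higher and 12 lower in MI_DCA than in MI_vehicle hearts by camera with the preset correlation, with 0 genes called in any list over all genes. With an estimated correlation no list passed. Cardiomyocyte markers (median 0.31, adjusted p = 2.04e-07), oxidative phosphorylation subunits (0.29, adjusted p = 2.46e-13), fatty acid oxidation genes (0.35, adjusted p = 3.56e-08), endothelial markers (0.12, adjusted p = 0.00066), circadian clock genes (0.33, adjusted p = 0.00136) and ion channel genes (0.15, adjusted p = 0.00363) ranked higher, each with an adjusted p = 0.59 with an estimated correlation. The ion channel call was lost with quantile normalization (0.105). Markers of infiltrating monocytes and macrophages (median -0.61, 22 of 22 below 0, adjusted p = 1.83e-05), activated fibroblast genes (-0.68, adjusted p = 8.47e-05), leukocyte adhesion genes (-0.51, adjusted p = 0.000149), and IL-1 signalling genes (-0.30, adjusted p = 0.00109) ranked lower. So did NF-kB pathway genes (-0.25, adjusted p = 0.00268), mast cell and dendritic cell markers (-0.73, adjusted p = 0.00366), glycolysis and hypoxia targets (-0.32, adjusted p = 0.00458) and pyroptosis genes (-0.26, adjusted p = 0.0161). All 8 had an adjusted p = 0.59 with an estimated correlation. Proinflammatory cytokine genes (-0.48, 20 of 20 below 0, adjusted p = 0.00363) and cell cycle genes (-0.53, adjusted p = 0.000169) had an adjusted p = 0.672 with an estimated correlation, ribosomal proteins (-0.24, adjusted p = 0.0022) 0.723 and neutrophil markers (-0.54, adjusted p = 0.0209) 0.678. Without MI_vehicle replicate 2, the neutrophil (0.111) and pyroptosis (0.0527) calls were lost, without MI_vehicle replicate 3 (0.112) or MI_DCA replicate 4 (0.0648) the neutrophil call, and without MI_DCA replicate 2 the glycolysis call (0.0829). Adjusted over the list alone, 4 class II MHC or related genes of the dendritic cell list and 2 resident macrophage, 2 PPAR target, 1 oxidative stress, 1 glucocorticoid and 1 endothelial gene were lower, and 1 endothelial gene was higher.

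The lists with no call included cardiac stress genes (median -0.53, adjusted p = 0.229), which were called lower with median-ratio scaling (0.0354), quantile normalization (0.00589) and without MI_DCA replicate 4 (0.0132) or 6 (0.0231). Interferon-stimulated genes had a median of -0.02 (adjusted p = 0.272), and without MI_DCA replicate 6 they ranked higher (6.07e-05), as they did without MI_vehicle replicate 2 (0.0397). Fibroblast markers (-0.17, adjusted p = 0.191) were called lower with quantile normalization (0.0217) and without MI_DCA replicate 1 (0.0427), 3 (0.0435) or 5 (0.0208). Heat shock genes (-0.01, adjusted p = 0.226) were called higher without MI_DCA replicate 1 (0.017), 3 (0.0298) or 5 (0.0208), and PPAR targets (0.20, adjusted p = 0.291) without MI_vehicle replicate 4 (0.034) or MI_DCA replicate 2 (0.0234). Resident macrophage markers (-0.19, adjusted p = 0.383) were called without MI_vehicle replicate 1 (0.0326), erythroid markers (-0.16, adjusted p = 0.804) without MI_vehicle replicate 2 (0.0302) and oxidative stress genes (-0.28, adjusted p = 0.191) with quantile normalization (0.00456). Bile acid receptor and handling genes (-0.13, adjusted p = 0.259), cAMP and CREB targets (0.00, adjusted p = 0.417), lymphocyte and NK markers (-0.36, 3 members, adjusted p = 0.191) and the other lists tested, with adjusted p from 0.185 to 0.983, gave no call. Smooth muscle, interferon, heat shock, glucocorticoid and acute phase genes ranked above other genes at medians below 0. The smooth muscle and interferon medians turned positive with median-ratio scaling (0.07 and 0.05) and quantile normalization (0.07 and 0.04). Those of heat shock and glucocorticoid genes did so with median-ratio scaling alone (0.06 each), against -0.05 and -0.04 with quantile normalization. The means of atrial (-0.09), skeletal muscle (-0.02) and cAMP genes (-0.08) were below 0 at a median above 0.

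Scored per heart, no list differed between MI_DCA and MI_vehicle hearts after adjustment over 41 scores (smallest adjusted exact permutation p = 0.315), and 3 had an unadjusted exact p under 0.05, those of mast cell and dendritic cell (0.0108), IL-1 signalling (0.0325) and glycolysis genes (0.0433). The monocyte and macrophage score was 3.98 ± 0.59 in MI_DCA and 4.59 ± 0.47 in MI_vehicle hearts (difference -0.62, 95% interval -1.31 to 0.08, unadjusted exact permutation p = 0.0714), and the cytokine score 2.63 ± 0.52 and 3.13 ± 0.54 (-0.51, 95% interval -1.19 to 0.18, exact permutation p = 0.13). The cardiomyocyte score was 10.1 ± 0.38 and 9.82 ± 0.35 (0.27, 95% interval -0.20 to 0.74, exact permutation p = 0.216). Hearts within each MI group spread widely along the first principal component of all 18 hearts, which held 70.3% of the variance. On it the sham hearts lay from -41.4 to -33.3, MI_vehicle replicate 4 at -15, MI_DCA replicates 1, 3 and 5 at -19.2, -25.5 and -14.5, and the other MI hearts from 16.7 to 55. The estimated depth of those 4 hearts was 10000000 to 11200000 mapped reads, and that of the other 8 MI hearts 11400000 to 13900000.

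**Figure D2:**
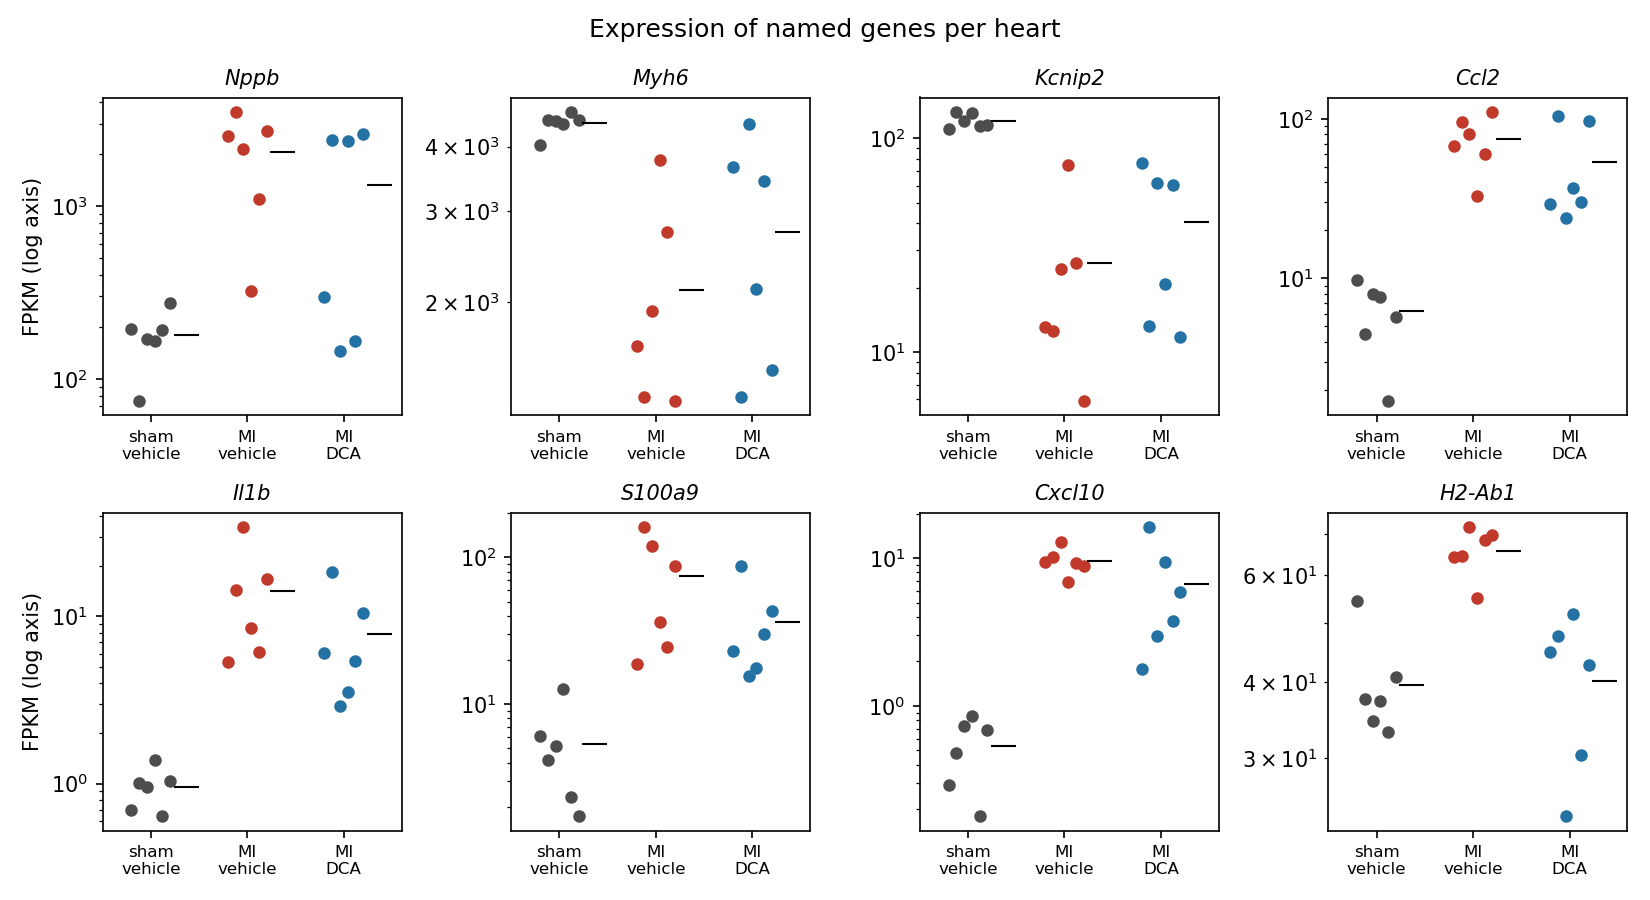
FPKM of 8 genes per heart (vertical axes, logarithmic) in the 3 groups (horizontal axes), 1 point per heart, with the group mean of FPKM as a horizontal mark. Nppb was 179 FPKM on average in sham, 2057 in MI_vehicle and 1331 in MI_DCA hearts.

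Across 12229 genes, which are not independent replicates, fold changes of MI_DCA over MI_vehicle ran opposite to those of MI_vehicle over sham_vehicle (Pearson r = -0.824, covariance -0.114). Both fold changes use the MI_vehicle hearts, with opposite sign, and 100 simulated unchanged groups against those hearts gave a mean r of -0.543 and a mean covariance of -0.0164. Of the 6991 genes called after infarction, 93.0% had an opposite sign, against 68.9% in the simulation. With the MI_vehicle hearts divided so that the 2 fold changes shared none, r averaged -0.642 over 20 divisions, from -0.822 to -0.071. Among all 924 regroupings of the 12 MI hearts, 108 (11.7%) gave a covariance at least as negative and 85 an opposite share at least as high. Their r ran from -0.943 to 0.766, whereas the simulated r had an SD of 0.0132. The simulation thus lacks the spread between real hearts, and its 68.9% understates what a regrouping of these hearts can give.

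**Figure D3:**
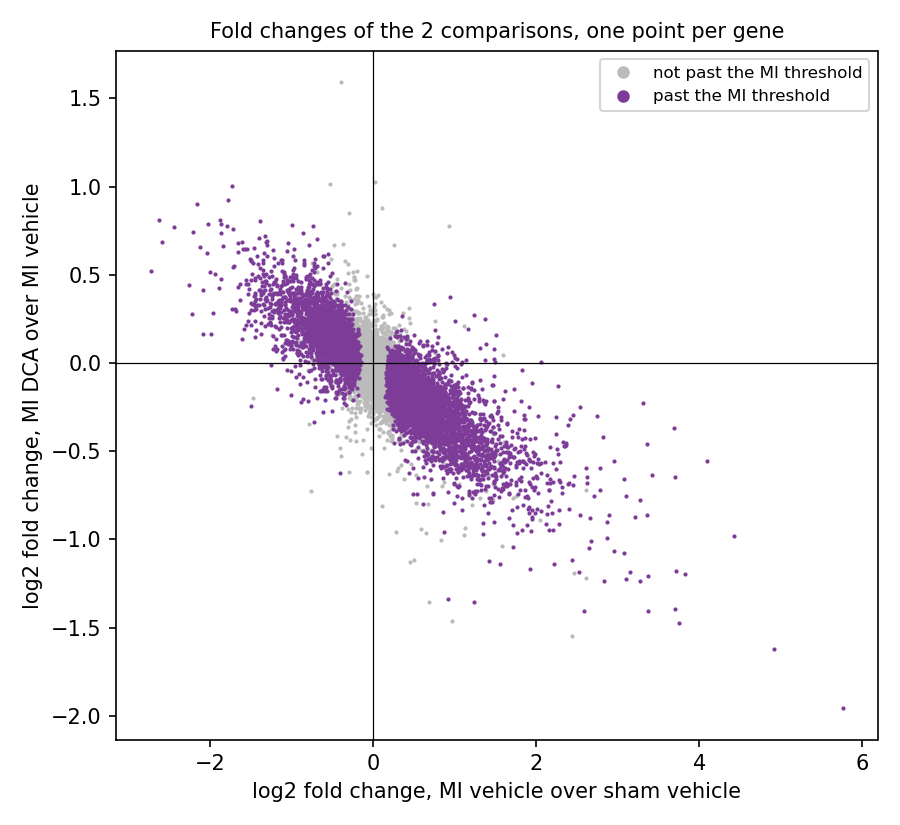
Log2 fold change of MI_DCA over MI_vehicle (vertical axis) against that of MI_vehicle over sham_vehicle (horizontal axis), 1 point per gene for 12229 genes, with genes called in the second comparison in purple. The points run from upper left to lower right (r = -0.824), part of which comes from the MI_vehicle hearts that both axes share.

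Infarcted hearts given DCA were also compared with sham hearts. Among genes with a mean of at least 10 FPKM, the largest rises were those of Sprr1a (log2 fold change 3.81, SE 1.07, adjusted p = 0.028) and Ankrd2, of the cardiac stress list (3.54, SE 0.91, adjusted p = 0.0219). Spp1, of the activated fibroblast list (3.45, SE 0.62), followed. Next came Ly6c2, of the monocyte list (3.32, SE 0.38, from 1.6 ± 0.854 FPKM in sham to 29.2 ± 24.5 in MI_DCA hearts), and Nmrk2, of the cardiac stress list (3.30, SE 0.92, adjusted p = 0.0273). Slfn4 (3.09, SE 0.43), Chil3 (3.06, SE 0.42) and Ccl7 (2.90, SE 0.39) completed the 8, and the adjusted p of these 3, Spp1 and Ly6c2 ranged from 0.00162 to 0.00799. The largest falls at that mean were those of A530016L24Rik (-1.95, SE 0.52), Kcnip2 (-1.90, SE 0.42), Mylk4 (-1.82, SE 0.38), Ces1d (-1.82, SE 0.44), Clec3b (-1.82, SE 0.61), Pdk4, which restrains glucose oxidation (-1.75, SE 0.28), Acot1 (-1.68, SE 0.39) and Art4 (-1.48, SE 0.48), with adjusted p from 0.00466 to 0.0474. Il1b (1.95, SE 0.32), Ccl2 (2.79, SE 0.41), S100a8 (1.88, SE 0.43) and S100a9 (2.50, SE 0.44) rose. Il6, Tnf and Cxcl2 lay below the filter and were higher in every MI_DCA heart than in any sham heart (exact permutation p = 0.00217 each), and Nlrp3 had an exact permutation p of 0.00433. Gpbar1 (0.238 ± 0.195 against 0.05 ± 0.0837 FPKM, exact permutation p = 0.0649), Nr1h4 (0.368 ± 0.36 against 0.567 ± 0.17, exact permutation p = 0.253) and Col1a1 (0.15, SE 0.23, adjusted p = 0.622) gave no call. Myh6 (-0.84, SE 0.28, adjusted p = 0.0442) passed and Nppb (2.04, SE 0.76, adjusted p = 0.0637) did not.

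Several of these calls lay near the threshold and were lost with 5 hearts in a group, at fold changes of the same direction. Those of Sprr1a (fold changes 3.14 to 3.95) and Nmrk2 (2.77 to 3.32) were lost without sham_vehicle replicate 2, 3 or 5 or MI_DCA replicate 2, 4 or 6 (adjusted p from 0.0514 to 0.0592), that of Ankrd2 without sham_vehicle replicate 5 (0.0504), and that of A530016L24Rik without sham_vehicle replicate 2 (0.0522) or 5 (0.0545) or MI_DCA replicate 4 (0.0531) or 6 (0.0509). The calls of Art4, Clec3b and Myh6 were lost whichever sham heart was left out (fold changes -1.54 to -1.44, -1.89 to -1.73 and -0.87 to -0.83) and without MI_DCA replicate 2, 4 or 6 (-1.31 to -1.18, -1.69 to -1.39 and -0.80 to -0.66), with adjusted p from 0.0567 to 0.101. Nppb passed without MI_DCA replicate 1 (0.0459), 3 (0.0202) or 5 (0.031). With array quality weights the fold changes themselves shrank, and Nmrk2 (3.30 to 1.51, adjusted p = 0.0813), Clec3b (-1.82 to -0.59, 0.234), Art4 (-1.48 to -0.55, 0.171) and Myh6 (-0.84 to -0.39, 0.0963) were not called. Sprr1a (2.24), Ankrd2 (2.12), A530016L24Rik (-0.99), Ces1d (-1), Kcnip2 (-1.10) and Acot1 (-1.01) stayed called at fold changes over 1.5 times smaller, and Nppb fell to 0.78. With quantile normalization Myh6 was not called (0.0577). The calls of Clec3b, Art4 and Myh6 were also lost with no filter on low values (0.0744, 0.0661 and 0.0883), those of Clec3b and Myh6 with all 18 libraries in one fit (0.0703 and 0.0508), those of Art4 and Myh6 with the number in the titles as a block (0.0554 and 0.0599), and that of Clec3b with a pseudocount of 0.1 (0.0519).

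By list, 14 ranked higher and 7 lower in MI_DCA than in sham hearts by camera with its preset correlation. Scores per heart differed for 24 of 41 lists after adjustment (exact permutation test, smallest adjusted p = 0.00555). Counts are of members past the filter (13 of 23 listed cytokine genes and 12 of 23 neutrophil markers), which favours rises from near 0. Interferon-stimulated genes led those that ranked higher (20 of 26 rose, 22 adjusted over the list alone, adjusted p = 3.2e-10), with monocyte and macrophage markers (15 of 20, 16 adjusted over the list alone, adjusted p = 2.58e-08) and cytokine genes (11 of 13, 12 adjusted over the list alone, adjusted p = 4.42e-07) after them. Leukocyte adhesion genes (16 of 21 rose and 1 fell, 17 and 1 adjusted over the list alone, adjusted p = 1.32e-06), neutrophil markers (11 of 12, 11 adjusted over the list alone, adjusted p = 1.46e-05) and cardiac stress genes (11 of 16, 15 adjusted over the list alone, adjusted p = 1.92e-05) followed, and all 6 had an adjusted p = 0.444 with an estimated correlation. Fatty acid oxidation genes (14 of 25 fell, 20 adjusted over the list alone, adjusted p = 3.2e-10), PPAR targets (7 of 15, 12 adjusted over the list alone, adjusted p = 3.24e-06), cardiomyocyte markers (8 of 24, 8 adjusted over the list alone with 1 higher, adjusted p = 8.17e-05) and ion channel genes (9 of 23, 9 adjusted over the list alone, adjusted p = 0.000221) ranked lower, each with an adjusted p = 0.444 with an estimated correlation. Oxidative phosphorylation subunits did as well (4 of 30 fell, 0 adjusted over the list alone, adjusted p = 8.17e-07, and 0.475 with an estimated correlation). Activated fibroblast (11 of 19 rose, 14 adjusted over the list alone, adjusted p = 2.18e-05), unfolded protein (14 of 20 rose and 1 fell, 14 and 2 adjusted over the list alone, adjusted p = 2.01e-05) and NF-kB genes (12 of 20 rose and 1 fell, 15 and 2 adjusted over the list alone, adjusted p = 0.000221) ranked higher as well. So did pyroptosis (5 of 11 rose, 6 adjusted over the list alone, adjusted p = 0.00096), IL-1 signalling (10 of 20 rose and 1 fell, 10 and 1 adjusted over the list alone, adjusted p = 0.00212) and apoptosis genes (10 of 22 rose, 10 and, lower, 1 adjusted over the list alone, adjusted p = 0.0129). All of these had an adjusted p = 0.444 with an estimated correlation. Ribosomal proteins (14 of 25 rose, 21 adjusted over the list alone, adjusted p = 3.92e-06, and 0.461 with an estimated correlation) and cell cycle genes (3 of 21 rose, 3 adjusted over the list alone, adjusted p = 0.00302, and 0.6 with an estimated correlation) completed the 14. Adipocyte and erythroid markers ranked lower (1 of 3 and 1 of 7 fell, 2 each adjusted over the list alone), with an adjusted p = 0.444 each with an estimated correlation. The adipocyte call (adjusted p = 0.0282) was lost with quantile normalization (0.0607), and the erythroid call (0.0187) without sham_vehicle replicate 1 (0.0963). Oxidative stress genes (0.0952) were called with median-ratio scaling (0.0472), quantile normalization (0.0289) or without sham_vehicle replicate 1 (0.0404), and heat shock genes (0.0843) with quantile normalization (0.0284) or without sham_vehicle replicate 5 (0.044) or MI_DCA replicate 1 (0.0224), 3 (0.0347) or 5 (0.0306). Anti-inflammatory genes (0.107) were called with quantile normalization (0.048) and fibroblast markers (0.107) without sham_vehicle replicate 4 (0.0458). Signs differed between median and mean for dendritic cell (-0.01 and 0.09), epicardial (-0.01 and 0.00), atrial (-0.22 and 0.15) and bile acid genes (0.15 and -0.04), and acute phase genes ranked lower at a median of 0.08.

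The count was 1830 higher and 987 lower genes of 11842 tested (23.8%), and 257 and 86 at a log2 fold change of at least 1. Higher genes made up 65.0% of those called as deposited, 47.8% with median-ratio scaling and 45.6% with quantile normalization. The counts moved by over 1.5 times without sham_vehicle replicate 2 (890 higher and 383 lower), 3 (1017 and 449), 4 (1156 and 506), 5 (740 and 315) or 6 (1078 and 481) and without MI_DCA replicate 2 (878 and 385), 4 (988 and 351) or 6 (851 and 328), and the count of lower genes without MI_DCA replicate 3 (1489). That more genes passed against sham in MI_vehicle than in MI_DCA hearts is not a test of DCA, which is the direct comparison above.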

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

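The test of less infarcted tissue, the definition of the hearts it concerns, the choice of the 4 class II genes and the splits fitted with array quality weights were chosen only after the results were seen. Of 261 groups of 6 hearts (46 genes and 41 scores), 15 held 1 heart far from the other 5 by Dixon's criterion, where chance gives about 13 for normally distributed values. Genes were judged on FPKM, which is skewed upward, and not on the log scale of the tests. High FPKM values are therefore flagged more readily and need not stand apart on the log scale. MI_vehicle replicate 4 had 75.19 FPKM of Kcnip2 (others 5.91 to 26.11), 34.04 of Lrtm1 (3.16 to 9.82), 12.71 of Maged2 (16.55 to 18.28) and a heat shock score of 6.744 (7.269 to 7.512). MI_vehicle replicate 3 had 19.34 FPKM of Cxcl2 (1.37 to 4.61), and MI_vehicle replicate 2 had 72.44 of Ly6c2 (19.37 to 34.47). MI_DCA replicate 2 had 77.73 FPKM of Ly6c2 (11.31 to 28.84) and 62.69 of Slfn4 (11.15 to 28.29), and MI_DCA replicate 6 an interferon score of 3.261 (4.163 to 4.661). Sham_vehicle replicate 1 had 4032 FPKM of Myh6 (4430 to 4668) and an oxidative phosphorylation score of 9.849 (9.534 to 9.606). The resident macrophage score of sham_vehicle replicate 5 was 3.121 (3.338 to 3.459) and the fibroblast score of sham_vehicle replicate 4 was 5.263 (5.432 to 5.532). The lymphocyte and NK score of MI_vehicle replicate 5 was 1.195 (0.878 to 0.997), and the acute phase score of MI_vehicle replicate 1 was 4.173 (4.719 to 5.045).

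MI_vehicle replicate 4 and MI_DCA replicates 1, 3 and 5 lay on the sham side of 0 on the first principal component. A first definition, by a cardiomyocyte score within the sham range, had taken in 0 MI hearts. Sham hearts under a wrong label are argued against by 4 of the 4 hearts lying above every sham heart in both the interferon and the monocyte score, although Il1b above sham had been seen before that test, and scaling by abundant transcripts by 4 of 4 staying on that side after median-ratio scaling. Less infarcted tissue in the apex sample stays open: these hearts ranked no higher than 4 of 12 in the cardiac stress, activated fibroblast and hypoxia scores, but that restates how they were picked, since the first component of the 12 MI hearts followed the infarction fold change (r = 0.906 across genes), and their interferon scores (4.16 to 4.62) were within the range of the other MI hearts (3.26 to 4.66) and above sham (2.85 to 3.41), which goes against an equal loss of every infarct signal. Their lower estimated depth and, for the 3 MI_DCA hearts, an effect of DCA also stay open and were not tested.

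Fold changes of MI_DCA over MI_vehicle ran opposite to those of MI_vehicle over sham_vehicle. The MI_vehicle hearts shared by both fold changes are argued against as the whole cause by a mean r of -0.6424 across genes over 20 divisions in which the fold changes shared no heart, although the r of single divisions went up to -0.071. A spread between infarcted hearts along 1 axis, present whatever the treatment, may give the pattern, since 11.69% of the 924 regroupings of the 12 MI hearts gave a covariance at least as negative. An effect of DCA opposite to that of infarction stays open and was not shown.

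The class II MHC genes H2-Aa, H2-Ab1 and H2-Eb1, which present antigen, and Cd74, which encodes their invariant chain, are called class II genes here. As a mean of these 4 genes they were lower in MI_DCA than in MI_vehicle hearts (5.42 ± 0.411 against 6.18 ± 0.128, difference -0.76, SE 0.18, exact permutation p = 0.00217, the smallest possible). Sham hearts measured 5.58 ± 0.231, so the MI_DCA mean lay below that of sham hearts. MI_DCA replicates 3 (4.73) and 5 (5.1) lay below every sham heart (5.37 to 6.03). The other MI_DCA hearts (5.57 to 5.76) lay within the sham range, and MI_DCA against sham was not tested for this mean. Of the 4 genes 0 were called over all genes (adjusted p from 0.402 to 0.407). They were members of a fixed list but were picked from it for their values, so that p is not that of a planned test. With the cardiomyocyte score as a covariate the difference stayed at -0.64 (SE 0.17, -3.752 SE), where the position of hearts on the cardiomyocyte axis as the whole cause predicts a value near 0. The genes were picked for their values in these same hearts, which inflates this value too, so it does not settle that question. A change in the number of cells that express these genes stays open here, and the test of it that was run is not reported. Markers of infiltrating monocytes and macrophages were lower too (median -0.61, 22 of 22 below 0, adjusted p = 0.59 by camera with an estimated correlation). With the cardiomyocyte score as a covariate their median was -0.22 (21 below 0, adjusted p = 0.789 by camera with an estimated correlation). An effect of DCA stays open as well.

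Of 100 splits of the 12 hearts into 6 and 6, only the real 1 gave as many genes for MI_vehicle against sham_vehicle (6991, against at most 1 in the others) and for MI_DCA against sham_vehicle (2817, against at most 2). A chance division of these hearts is thus an unlikely source of either count. Splits that mix MI and sham hearts raise the spread within groups, which itself makes counts near 0 likely in them. For MI_DCA against MI_vehicle the real count was 0, which all 100 splits reach by construction, so they decide nothing there. Of the others 3 gave any gene, and the highest counts were 5432 and 3128. Those splits put MI_DCA replicates 2 and 6 with MI_vehicle replicates 1, 2, 5 and 6, and MI_DCA replicates 2 and 4 with MI_vehicle replicates 1, 2, 3 and 6, which points to a structure of the samples other than treatment. With array quality weights 19 of 100 splits gave at least the real 5370 genes (highest other 7840), so chance was not excluded.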

How the results depend on the processing

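Median-ratio scaling, quantile normalization, array quality weights, the minimum mean of 10 FPKM and the cardiomyocyte score as a covariate were chosen only after the results were seen. In MI_vehicle against sham_vehicle, 4583 higher and 2408 lower genes became 2430 and 1526 with a mean FPKM of at least 10 and 785 and 292 at a log2 fold change of at least 1, where fewer genes qualify. The lower genes became 3693 with quantile normalization. Of the calls in both fits, 82.8% were kept with median-ratio scaling and 79.8% with quantile normalization. Without each heart in turn the counts stayed between 4017 and 4979 higher and between 2038 and 2740 lower. In MI_DCA against MI_vehicle the count of 0 and 0 became 1623 and 3747 with array quality weights. It was 0 higher and from 0 to 1 lower without each heart in turn, and 0 and 0 in every other alternative run, the covariate included. In MI_DCA against sham_vehicle, 1830 higher and 987 lower genes became 1124 and 572 with the number in the titles as a block and 257 and 86 at a log2 fold change of at least 1. The higher genes became 1144 with a mean FPKM of at least 10, and the lower genes 1555 with quantile normalization and 565 with weights. Without each heart in turn they ranged from 740 to 2596 higher and from 315 to 1489 lower. With an estimated correlation the called lists became 0 higher and 0 lower in each of the 3 comparisons, from 15 and 7, 6 and 12, and 14 and 7. Except where the construction is named, the cause was not tested.

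No named gene reversed under any alternative run. Over the named genes and alternatives together, MI_vehicle against sham_vehicle lost a call in 26 cases and kept its side of the threshold in 2285. MI_DCA against sham_vehicle lost 57, gained 3 and kept 399, and MI_DCA against MI_vehicle gained 20, all with array quality weights, and kept 386. The weights stopped short of their convergence tolerance in some fits. Hearts with the same number correlated from -0.557 to 0.77 after centring by group and mostly resembled another number more, so the block rests on a shared number alone. The planned tests with DESeq2, voom, edgeR's scalings and a filter in counts per library were not run, since they need counts, and scaling by library size alone is that of FPKM as deposited. Without counts, what depth limits among genes of low expression could not be given as an interval.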

Other observations

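All tests in this part were chosen only after the results were seen. Across both infarcted groups, 632 of 12229 genes were higher in each of the 12 MI hearts than in any of the 6 sham hearts and 203 were lower in each, 6.83% together, where chance gives 0.0108%. The widest separations upward were those of Ly6c2, at 11.31 to 77.73 FPKM in MI hearts and 0.55 to 2.84 in sham hearts, the chemokine genes Ccl7 (30.7 to 103.89 against 1.96 to 10.63) and Ccl2, the protease gene Adam8 and the myeloid gene Plac8. Kcnip2 lay at 5.91 to 76.31 FPKM in MI hearts and at 110.35 to 132.94 in sham hearts. Of the fixed lists, 15 of 22 monocyte and macrophage markers, 13 of 20 cytokine and chemokine genes, 12 of 22 leukocyte adhesion genes, 11 of 26 interferon-stimulated genes, 11 of 20 unfolded protein response genes and 8 of 16 neutrophil markers were higher in every MI heart, and 7 of 25 fatty acid oxidation genes lower. Of 16 cardiac stress genes 4 were higher, and of 24 cardiomyocyte markers 2 lower.

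With the cardiomyocyte score of each heart as a covariate, 0 genes were higher and 0 lower in MI_DCA than in MI_vehicle hearts in limma (smallest adjusted p = 0.0963, and 1588 genes at an unadjusted p under 0.05). By list, 4 ranked higher: heat shock genes (median 0.16, 2 higher adjusted over the list alone, adjusted p = 6.2e-06), oxidative phosphorylation subunits (0.03, adjusted p = 0.00275), endothelial markers (0.07, adjusted p = 0.0346) and unfolded protein response genes (0.07, adjusted p = 0.0389). PPAR targets ranked lower (-0.48, 7 of 15 lower adjusted over the list alone, adjusted p = 0.000207), where their median without the covariate was 0.20. So did fibroblast markers (-0.28, adjusted p = 0.0249), mast cell and dendritic cell markers (-0.43), activated fibroblast genes (-0.31) and monocyte and macrophage markers (-0.22), the last 3 at an adjusted p of 0.0372, and glycolysis (-0.17) and IL-1 signalling genes (-0.16), both at 0.0389. All of these had an adjusted p = 0.789 with an estimated correlation. Calls made without the covariate were lost for leukocyte adhesion (0.0541), cardiomyocyte (0.173, the markers of the covariate itself), cell cycle (0.194), circadian (0.224), pyroptosis (0.324), neutrophil (0.352), ion channel (0.41), NF-kB (0.414), cytokine (0.554), ribosomal (0.611) and fatty acid oxidation genes (0.956). The heat shock and unfolded protein medians without the covariate were -0.01 and -0.14, and those of ion channel and fatty acid oxidation genes went from 0.15 to -0.15 and from 0.35 to -0.03. The score is itself measured after treatment, so these values describe hearts of like cardiomyocyte score and not the whole effect of DCA.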
